A study of Arabidopsis thaliana with 8 samples.

How the data were processed

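RNA sequencing libraries of Arabidopsis thaliana seedlings (ecotype Col, 4.5 days old) were compared between 4 groups of 2 libraries: dark wild type, and wild type, phyB and phyAB after 1 h of red light at 50 µmol per square metre per second. Per the labels' protocols, seeds received 12 h of white light and a further 21 h to induce germination on medium with 1% sucrose, and then 4 days of darkness at 22 °C. The series' design text speaks of dark and red-treated samples of each genotype, and dark mutant libraries are not analysed here. Per the file headers, the deposited files give for each gene model the number of reads (counts) and the RPKM. The reads are whole numbers that were not normalized. The RPKM values deposited by the authors scale the reads by the length of the gene model and by the total of the library. Dividing the reads by them gave the same whole length, within 0.05, in every library for 19105 of 19105 gene models checked. Genome build TAIR10 is given in the submitters' processing notes. The aligner, the counting tool, the annotation release, the handling of reads that fit several genes and the strandedness of the libraries are not given in the sources used here.

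The files list 27416 gene models, one per gene. Of these, 2868 had 0 reads in every library and 26719 have an entry in the annotation of the TAIR10.1 assembly, the reference used here for symbols, neighbours and positions. Total counts were 20045824 and 18714337 in WT dark, 19760675 and 16326741 in WT red, 15926547 and 22116924 in phyB red and 21699222 and 16619502 in phyAB red. Plastid genes took 0.211% to 0.279% of the reads. The root gene PYK10 alone took 1.11% to 1.78%.

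Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough reads were kept by filterByExpr with a minimum count of 10, which left 20716, and libraries were scaled by the trimmed mean of M-values (TMM). One model with 4 group means and no replicate term was fitted to all 8 libraries, and 6 contrasts were tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. Sharing the spread between groups was chosen because 2 libraries per group leave few degrees of freedom. The lists of genes were tested with camera (limma 3.58.1, two-sided) at a preset inter-gene correlation of 0.01, with adjustment over all 150 tests of 25 lists in 6 contrasts. A correlation estimated per list and the fry test were computed beside it. Of 103 list calls, 53 held with an estimated correlation, and median and test did not disagree in sign for any call. The fry test asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The lists hold 406 genes, of which 395 were tested. CPM values are reads scaled to the library total and by TMM.

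The comparisons, the test, the gene lists, the rule for the genes to name and the alternatives were chosen before the data were examined, except where noted. That rule takes PHYA and PHYB, and in the first 4 contrasts the 8 genes with the highest and the 8 with the lowest fold change among genes past the threshold with groups that do not overlap and a mean of at least 5 CPM, with at most 2 per direction that have no symbol. It also takes up to 4 members of each list with the largest change, and 24 preset light-response genes. The text names a part of the genes it takes. A gene with 0 reads in a group is given as at least so many fold against a floor of 3 counts over the group, and one with 1 to 3 reads as a ratio with a 95% exact binomial counting interval. Intervals and floors cover counting error only. The part of the wild-type response seen in a mutant is (mutant − WT dark) / (WT red − WT dark) on log2 CPM with 0.1 added, over genes changed at least 2-fold. Values for shared control libraries come from 20 simulations of unchanged groups.

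Per gene, the variance between the 2 libraries of a group was 1.35 to 1.48 times that of counting error alone, and the common biological coefficient of variation was 1.59%. The labels do not state that replicates are separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and small changes pass easily.

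The test was tried on simulated data for the 20716 genes with the real means and depths and 50 changed genes per fold size. The changed genes were drawn from those with a mean of at least 1 CPM, and the other 20516 genes were unchanged. For phyB red against WT red it recovered 50%, 80%, 90% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, and 3.61% of its calls were false. For phyAB red against WT red it recovered 48%, 80%, 92% and 100%, and 4.19% of its calls were false. In the data, 27.1% and 45.0% of genes were called in these 2 comparisons, so recovery of small changes may differ there. The simulated spread is that between these libraries, so the false shares do not cover variation between separate cultures.

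Alternatives were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 Wald test (version 1.42.0), fits of only the groups compared, a replicate block, a test against a 2-fold change (glmTreat), leaving out organelle genes, limma-voom and leaving out each library in turn. For the part of the response they were selection of genes in some libraries and measurement in others, and fixed lists. For the overlap it was an adjusted p of 0.01. A fixed biological coefficient of variation of 0.1 and the counts of genes changed at least 2-fold were added after seeing the data. Sets of DNA damage and cell division genes were composed after seeing the data as well. Not every member of these sets is reported here. Alternatives planned for normalized values were not needed, since the counts were tested. Nucleotide differences between the genotypes were not analysed here.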

Results

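RNA sequencing was carried out on dark-grown (etiolated) Arabidopsis thaliana seedlings of the Col ecotype to follow the transcript response to red light and its dependence on the red and far-red light receptors phytochrome A (PHYA) and phytochrome B (PHYB). Seedlings 4.5 days old had been kept in the dark for 4 days at 22 °C on medium with 1% sucrose. They then either stayed in the dark or received red light at 50 µmol per square metre per second for 1 h. The samples form 4 groups of 2 libraries each: dark wild type (WT dark), red-treated wild type (WT red), the red-treated phyB mutant (phyB red) and the red-treated phyA phyB double mutant (phyAB red). Dark libraries of the mutants are not analysed here, so each genotype comparison includes differences that may already exist in darkness. The libraries held 15926547 to 22116924 reads assigned to 27416 gene models, and 20716 genes had enough reads to be tested. Values below are log2 fold changes ± SE with n = 2 libraries per group unless stated otherwise. The SE is the size of the log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. It is not the spread of the 2 libraries, and for large changes it can be smaller than counting error alone.

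PHYA and PHYB transcripts were measured first in every library as a check of the genotypes. PHYA (AT1G09570, chromosome 1, 3095160 to 3100819 in TAIR10.1) stood at 834 and 828 CPM (reads scaled to library size) in the WT dark libraries and at 463 and 471 CPM in the WT red libraries. It stood at 703 and 703 CPM in phyB red and at 124 and 123 CPM in phyAB red. PHYB (AT2G18790, chromosome 2, 8139756 to 8144461) stood at 80.7 and 81.4 CPM in WT dark, 96.0 and 95.2 CPM in WT red, 62.3 and 64.3 CPM in phyB red and 52.9 and 50.4 CPM in phyAB red. Relative to WT red, PHYB fell in phyB red (-0.59 ± 0.04) and in phyAB red (-0.88 ± 0.05), and PHYA fell in phyAB red (-1.92 ± 0.03) but rose in phyB red (0.59 ± 0.02). Reads of both genes remained in the mutants, and the labels do not describe the alleles. These levels go in the direction of the labels, without showing that either protein was absent. In a principal component analysis, the 2 libraries of each group lay next to each other, and the first 3 components took up 53.4%, 24.9% and 10.4% of the variance.

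**Figure D1:**
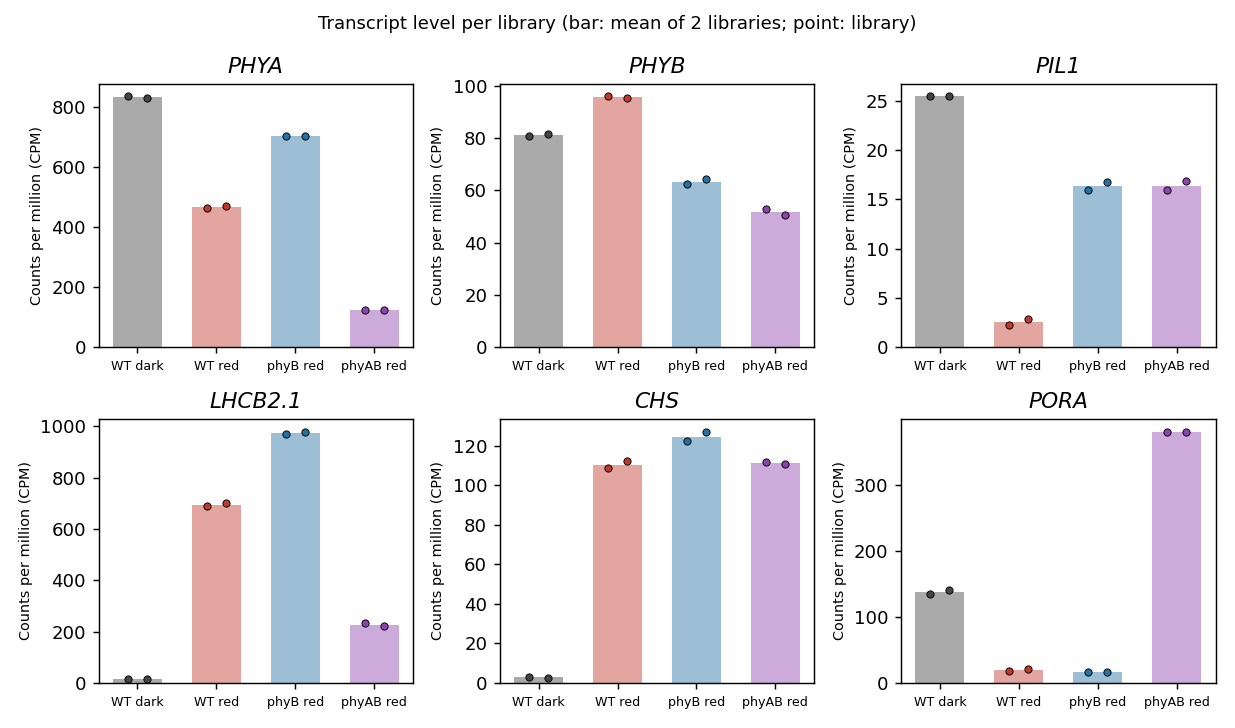
Transcript level in CPM (vertical axes, each starting at 0) of PHYA, PHYB, PIL1, LHCB2.1, CHS and PORA in the 4 groups; bars are means of 2 libraries and points are single libraries. PHYA lay at 124 and 123 CPM in phyAB red against 463 and 471 CPM in WT red.

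The comparison of WT red with WT dark shows how 1 h of red light changed transcript levels in etiolated wild-type seedlings. Nuclear genes of the light-harvesting antenna, which hold chlorophyll around the photosystems, rose together. Of 20 tested antenna genes, 19 were higher and 0 lower (20 and 0 adjusted over the list alone, median log2 3.03, adjusted p = 3.51e-19). The highest values were those of LHCB1.1 (AT1G29920, 6.69 ± 0.06), LHCB1.4 (AT2G34430, 6.22 ± 0.06), LHCB2.2 (AT2G05070, 6.17 ± 0.05) and LHCB2.1 (AT2G05100, 5.48 ± 0.05). The LHCB1 and LHCB2 copies are nearly identical in sequence, so the split of reads between them is uncertain. All 26 photosystem subunit and Rubisco small subunit genes were higher (26 and 0 adjusted over the list alone, median log2 2.70, adjusted p = 3.48e-23). Among them was the photosystem I gene PSAH2 (4.14 ± 0.05). Of 26 chlorophyll synthesis genes, 21 were higher and 2 lower (21 and 2 adjusted over the list alone, median log2 1.2, adjusted p = 2.56e-09). The tetrapyrrole genes HEMA1 (1.69 ± 0.04), GUN5 (2.54 ± 0.03) and GUN4 (3.46 ± 0.06) rose, whereas PORA, the protochlorophyllide oxidoreductase of etiolated tissue, fell (-2.81 ± 0.06). All 8 photoprotection genes rose (8 and 0 adjusted over the list alone, median log2 2.50, adjusted p = 1.55e-08), with the early light-induced proteins ELIP1 at 5.38 ± 0.10 and ELIP2 at 5.19 ± 0.08. All 13 genes of plastid isoprenoid and carotenoid enzymes rose as well (13 and 0 adjusted over the list alone, median log2 0.93, adjusted p = 6.53e-08). All 10 nuclear regulators of chloroplast development were higher (10 and 0 adjusted over the list alone, median log2 1.35, adjusted p = 3.16e-07). The list was led by the GATA factor CGA1 (4.33 ± 0.31) and the plastid sigma factor SIG5 (3.93 ± 0.10).

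Genes of flavonoid synthesis, which makes ultraviolet-absorbing pigments, rose in 15 of 17 tested members with 0 lower (15 and 0 adjusted over the list alone, median log2 2.26, adjusted p = 2.61e-08). Chalcone synthase, CHS (AT5G13930), rose by 5.29 ± 0.08 and the flavonol synthase FLS1 by 4.62 ± 0.26. LDOX, which acts late in anthocyanin synthesis, had 0 reads in WT dark and 85 in WT red, at least 31.0-fold higher against a floor of 3 counts over the group. Of 18 bZIP and B-box light-signalling factors, 11 were higher and 5 lower (11 and 5 adjusted over the list alone, median log2 1.46, adjusted p = 0.0123, adjusted p = 0.0812 with an estimated correlation). HY5, a factor that promotes light-type growth, rose by 0.80 ± 0.07, its homologue HYH by 3.40 ± 0.15, BBX25 by 5.03 ± 0.15 and BBX30 by 5.12 ± 0.39, while BBX23 fell (-5.21 ± 0.37). SPA1, a partner of the ubiquitin ligase COP1, rose (1.97 ± 0.04), as did RUP2 (3.33 ± 0.13), and FHY1 (-1.08 ± 0.07) and FHL (-1.49 ± 0.18), which carry phytochrome A into the nucleus, fell. Their list of 18 phytochrome signalling genes had 9 higher and 7 lower and did not pass as a group (9 and 7 adjusted over the list alone, median log2 0.13, adjusted p = 0.431). In the phytochrome interacting factor (PIF) family, 5 of 7 genes were higher and 2 lower (5 and 2 adjusted over the list alone, median log2 1.31, adjusted p = 0.0239, adjusted p = 0.194 with an estimated correlation). PIF7 stood at 3.03 ± 0.19, PIF5 at 1.33 ± 0.06 and PIF4 at 1.31 ± 0.05. Genes of heat shock proteins were higher in 6 of 8 tested members and lower in 1 (6 and 1 adjusted over the list alone, median log2 2.15, adjusted p = 0.00272, adjusted p = 0.0681 with an estimated correlation).

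Genes known to be activated by PIFs fell. Of 19 genes of this list, 0 were higher and 17 lower (0 and 17 adjusted over the list alone, median log2 -1.49, adjusted p = 9.08e-13). PIL1 (AT2G46970), a marker of shade and darkness, fell (-3.33 ± 0.13), as did the cell wall enzyme gene XTH15 (-3.55 ± 0.04), the Aux/IAA gene IAA29 (-2.44 ± 0.18) and ACS8 (-3.39 ± 0.26), which encodes an enzyme of ethylene synthesis. HFR1 did not pass (-0.04 ± 0.03, adjusted p = 0.33). Of the 26 small auxin up RNA (SAUR) genes, 22 were lower and 1 higher (1 and 22 adjusted over the list alone, median log2 -1.11, adjusted p = 3.83e-09). SAUR22 stood at -2.26 ± 0.12. Aux/IAA and GH3 genes were lower in 19 of 29 and higher in 3 (3 and 19 adjusted over the list alone, median log2 -0.31, adjusted p = 3.03e-05, adjusted p = 0.0521 with an estimated correlation). GH3.3 stood at -2.45 ± 0.12. Ethylene genes were lower in 12 of 17 and higher in 2 (2 and 12 adjusted over the list alone, median log2 -1.13, adjusted p = 7.96e-06). They included ACS5 (-2.35 ± 0.11) and the receptor gene ETR2 (-2.24 ± 0.10). Expansin and xyloglucan enzyme genes were lower in 17 of 26 and higher in 8 (8 and 17 adjusted over the list alone, median log2 -0.53, adjusted p = 0.00815, adjusted p = 0.0703 with an estimated correlation). Brassinosteroid genes were lower in 8 of 12 and higher in 2 (3 and 8 adjusted over the list alone, median log2 -0.21, adjusted p = 0.0342, adjusted p = 0.159 with an estimated correlation). All 6 genes of storage lipid use were lower (0 and 6 adjusted over the list alone, median log2 -0.42, adjusted p = 0.000595, adjusted p = 0.0518 with an estimated correlation), with isocitrate lyase, ICL, at -1.23 ± 0.03.

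Outside these lists, the genes with the highest fold changes included SDR1 (AT3G61220), with 0 reads in WT dark and 284 in WT red, at least 104-fold higher. AT1G26761 had 2 reads in WT dark and 282 in WT red, 154-fold higher with a 95% counting interval of 42.3 to 1280. The carboxypeptidase-like gene scpl10 (AT2G23000, 6.77 ± 0.29) and the aldolase gene FBA5 (AT4G26530, 6.53 ± 0.34) also rose. Among genes with a mean of at least 5 CPM, the most strongly reduced were GRF7 (AT5G53660, -4.81 ± 0.18), which encodes a growth-regulating factor, the cytochrome P450 gene CYP96A5 (AT2G21910, -4.33 ± 0.22) and AT5G02540 (-4.30 ± 0.16). Clock genes were higher in 17 of 31 and lower in 10 and did not pass as a list (17 and 10 adjusted over the list alone, median log2 0.30, adjusted p = 0.075). PRR9 stood at 1.38 ± 0.14, GI at 0.79 ± 0.04 and LHY at -0.65 ± 0.05. The lists of gibberellin genes (6 and 8 adjusted over the list alone, median log2 -0.02, adjusted p = 0.642), photoreceptors (4 and 2 adjusted over the list alone, median log2 0.03, adjusted p = 0.709), touch and wound genes (5 and 6 adjusted over the list alone, median log2 0.02, adjusted p = 0.836), root genes (1 and 4 adjusted over the list alone, median log2 -0.34, adjusted p = 0.138) and seed storage genes (1 and 0 adjusted over the list alone, median log2 0.05, adjusted p = 0.983) did not pass. The stomatal lineage list did not pass either (4 and 0 adjusted over the list alone, median log2 0.92, adjusted p = 0.0692), but passed with 1 library left out, with adjusted p = 0.0207 without WT dark replicate 2, 0.0379 without WT red replicate 1 and 0.0485 without WT red replicate 2.

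Across all 20716 tested genes, 4987 were higher and 4709 lower in WT red than in WT dark at an adjusted p under 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1471 were higher and 559 lower by at least 2-fold. The largest adjusted p among the genes named as changed in this comparison was 1.22e-11 (for FHL). Libraries of a group differed by little more than counting error, so calls reached log2 changes as small as 0.03. Tested against a 2-fold change, 951 genes were higher and 245 lower.

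**Figure D2:**
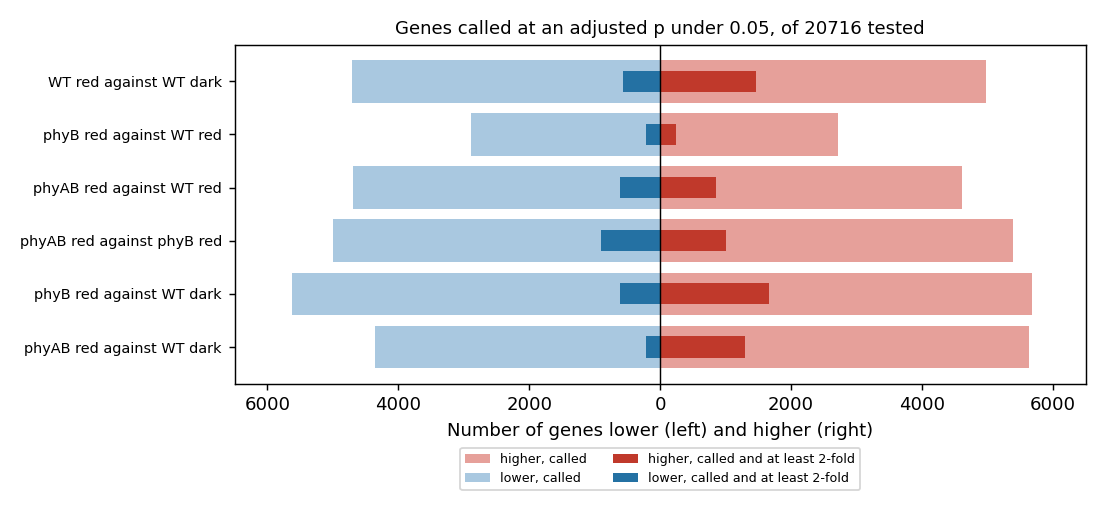
Number of genes higher (to the right) and lower (to the left) in each of the 6 comparisons, with pale bars for genes at an adjusted p under 0.05 and dark bars for those that also changed at least 2-fold. phyB red differed from WT red at the fewest genes, with 241 higher and 219 lower by at least 2-fold.

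The comparison of phyB red with WT red sets the phyB line against wild type after red light, and includes any other difference between these lines. PIF-induced and auxin-responsive genes were higher in phyB red, and photosynthesis genes were not lower. Of 19 PIF-induced genes, 18 were higher and 0 lower (18 and 0 adjusted over the list alone, median log2 1.05, adjusted p = 4.51e-18). They included PIL1 (2.69 ± 0.14), ACS8 (2.31 ± 0.30), IAA29 (2.07 ± 0.19) and PAR1 (1.89 ± 0.12). IAA19 was 2.38-fold higher. Among the 26 SAUR genes, 25 were higher and 0 lower (25 and 0 adjusted over the list alone, median log2 1.53, adjusted p = 4.19e-22), with SAUR15 (2.44 ± 0.20), SAUR22 (2.38 ± 0.12) and SAUR23 (2.18 ± 0.13) at the top. SAUR22 and SAUR23 are near-identical neighbours, so the split of reads between them is uncertain. Aux/IAA and GH3 genes were higher in 19 of 29 and lower in 1 (20 and 1 adjusted over the list alone, median log2 0.33, adjusted p = 9.98e-09). GH3.1 stood at 2.09 ± 0.20. Cell wall expansion genes were higher in 17 of 26 and lower in 3 (17 and 4 adjusted over the list alone, median log2 0.23, adjusted p = 1.40e-05). XTH15 rose (1.67 ± 0.05) and the expansin gene EXPA2 fell (-1.96 ± 0.28).

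Photosynthesis genes were slightly higher in phyB red than in WT red. Antenna genes were higher in 19 of 20 and lower in 0 (19 and 0 adjusted over the list alone, median log2 0.34, adjusted p = 7.59e-12). LHCB2.1 stood at 0.49 ± 0.01. All 26 photosystem and Rubisco genes were higher (26 and 0 adjusted over the list alone, median log2 0.26, adjusted p = 1.56e-12). Chlorophyll synthesis genes were higher in 19 of 26 and lower in 0 (21 and 1 adjusted over the list alone, median log2 0.20, adjusted p = 1.92e-06), although PORA did not pass (-0.20 ± 0.09, adjusted p = 0.0735). All 8 photoprotection genes were higher (8 and 0 adjusted over the list alone, median log2 0.35, adjusted p = 6.37e-06). ELIP2 stood at 1.32 ± 0.03 and ELIP1 at 1.21 ± 0.04. Carotenoid enzyme genes were higher in 8 of 13 and lower in 1 (9 and 1 adjusted over the list alone, median log2 0.23, adjusted p = 0.00241, adjusted p = 0.0589 with an estimated correlation). Phytochrome signalling genes were higher in 11 of 18 and lower in 0 (12 and 0 adjusted over the list alone, median log2 0.29, adjusted p = 8.62e-07). They included RUP1 (1.06 ± 0.07). Photoreceptor genes, a list that holds PHYA and PHYB, were higher in 6 of 9 with PHYA among them and lower in 1, PHYB (6 and 1 adjusted over the list alone, median log2 0.23, adjusted p = 0.0212, adjusted p = 0.106 with an estimated correlation), with the blue light receptor PHOT1 at 0.88 ± 0.03. The plastid regulators did not pass as a list (4 and 1 adjusted over the list alone, median log2 0.14, adjusted p = 0.148), and CGA1 was lower (-1.0 ± 0.19). CHS (0.18 ± 0.04) was slightly higher, and HY5 was too (0.25 ± 0.06), but not without WT red replicate 1 (adjusted p = 0.0806) or phyB red replicate 1 (adjusted p = 0.0728), while PIF4 (-0.05 ± 0.04, adjusted p = 0.476), SPA1 (0.07 ± 0.03, adjusted p = 0.073) and GI (-0.01 ± 0.04, adjusted p = 0.894) did not pass.

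Lower in phyB red were 12 of 31 clock genes, with 1 higher (1 and 13 adjusted over the list alone, median log2 -0.14, adjusted p = 0.00219, adjusted p = 0.053 with an estimated correlation), and 9 of 17 touch and wound genes, with 3 higher (3 and 9 adjusted over the list alone, median log2 -0.32, adjusted p = 0.0092, adjusted p = 0.0785 with an estimated correlation), including the zinc finger gene ZAT10 (-1.03 ± 0.11). Heat shock genes were lower in 5 of 8 and higher in 0 (0 and 5 adjusted over the list alone, median log2 -0.53, adjusted p = 0.00604, adjusted p = 0.0794 with an estimated correlation), and genes of storage lipid use were lower in 4 of 6 and higher in 1 (1 and 4 adjusted over the list alone, median log2 -0.23, adjusted p = 0.0259, adjusted p = 0.116 with an estimated correlation). The flavonoid list did not pass (5 and 6 adjusted over the list alone, median log2 -0.10, adjusted p = 0.29), although the anthocyanin genes PAP1 (-1.84 ± 0.29) and LDOX (-1.56 ± 0.34) were lower, the latter not without WT red replicate 1 (adjusted p = 0.0683). Among genes with a mean of at least 5 CPM, those with the highest changes were AT2G01008 (3.54 ± 0.15) and DML1 (AT2G36490, 2.95 ± 0.08), which encodes a DNA demethylase. Among those with the lowest were AT5G37990 (-3.05 ± 0.06), the chaperone gene of the endoplasmic reticulum BIP3 (AT1G09080, -2.47 ± 0.15), AT5G04120 (-2.38 ± 0.06), EXPA16 (AT3G55500, -2.35 ± 0.12) and the neighbours HEI10 (AT1G53490, -2.15 ± 0.10) and MRD1 (AT1G53480, -2.15 ± 0.12). The strand of the reads is not given, so reads of the last 2 genes may not be separable. The ethylene list did not pass (7 and 4 adjusted over the list alone, median log2 0.10, adjusted p = 0.074), but had an adjusted p = 0.0257 without WT red replicate 2 and 0.0468 without phyB red replicate 1. The B-box list did not pass (7 and 0 adjusted over the list alone, median log2 0.12, adjusted p = 0.0702) and had an adjusted p = 0.0402 without WT red replicate 1. The stomatal lineage list, with 1 of 6 genes higher, passed (1 and 0 adjusted over the list alone, median log2 0.19, adjusted p = 0.0422, adjusted p = 0.164 with an estimated correlation) and did so without WT red replicate 1 (adjusted p = 0.0228). It no longer passed without any 1 of the other 7 libraries, with adjusted p from 0.0599 to 0.21. Brassinosteroid, gibberellin, root, seed storage and PIF family lists did not pass.

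Across all tested genes, 2712 were higher and 2896 lower in phyB red than in WT red in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, of which 241 and 219 changed by at least 2-fold. The DESeq2 Wald test gave 1740 higher and 1912 lower. The largest adjusted p among the genes named as changed was 0.000722 (for HY5).

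The comparison of phyAB red with WT red sets the phyA phyB line against wild type after red light, and likewise includes any other difference between these lines. Photosynthesis genes were lower in phyAB red, in contrast to phyB red. Antenna genes were lower in 19 of 20 and higher in 0 (0 and 19 adjusted over the list alone, median log2 -1.2, adjusted p = 4.22e-16). They included LHCB1.4 (-2.06 ± 0.03), LHCA1 (-2.02 ± 0.02) and LHCB2.1 (-1.62 ± 0.02). All 26 photosystem and Rubisco genes were lower (0 and 26 adjusted over the list alone, median log2 -1.22, adjusted p = 1.54e-20). Of 26 chlorophyll synthesis genes, 3 were higher and 20 lower (4 and 20 adjusted over the list alone, median log2 -0.45, adjusted p = 1.15e-05). HEMA1 (-0.94 ± 0.03) and GUN5 (-0.82 ± 0.03) were lower, whereas PORA (4.28 ± 0.05) and PORB (1.70 ± 0.03) were higher. Photoprotection genes were lower in 7 of 8, with ELIP2 at -1.17 ± 0.05, and higher in 1, ELIP1 at 0.24 ± 0.04 (1 and 7 adjusted over the list alone, median log2 -1.26, adjusted p = 5.30e-05). Carotenoid enzyme genes were lower in 11 of 13 and higher in 0 (0 and 11 adjusted over the list alone, median log2 -0.54, adjusted p = 3.93e-06). Plastid regulators were lower in 9 of 10 and higher in 0 (0 and 9 adjusted over the list alone, median log2 -0.88, adjusted p = 7.19e-06, adjusted p = 0.0562 with an estimated correlation). SIG5 stood at -1.97 ± 0.07. The light-signalling factors HY5 (-1.09 ± 0.07), HYH (-1.28 ± 0.11) and BBX25 (-1.93 ± 0.10) were lower, in a list with 12 of 18 lower and 4 higher (4 and 12 adjusted over the list alone, median log2 -1.01, adjusted p = 0.00746, adjusted p = 0.073 with an estimated correlation). Other genes lower in phyAB red were PIF4 (-1.17 ± 0.05), PIF5 (-1.16 ± 0.06) and SPA1 (-1.36 ± 0.04), as was the Calvin cycle regulator CP12-2 (AT3G62410, -2.38 ± 0.08).

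PIF-induced genes were higher in 18 of 19 and lower in 1 (18 and 1 adjusted over the list alone, median log2 1.17, adjusted p = 2.32e-10). PIL1 stood at 2.69 ± 0.14, IAA29 at 2.41 ± 0.18, XTH15 at 2.25 ± 0.04 and ACS8 at 2.46 ± 0.30. SAUR genes were higher in 19 of 26 and lower in 3 (19 and 3 adjusted over the list alone, median log2 0.53, adjusted p = 4.20e-05). Aux/IAA and GH3 genes were higher in 17 of 29 and lower in 7 (17 and 7 adjusted over the list alone, median log2 0.30, adjusted p = 0.00353, adjusted p = 0.102 with an estimated correlation). GH3.3 stood at 2.68 ± 0.12. Ethylene genes were higher in 10 of 17 and lower in 1 (10 and 2 adjusted over the list alone, median log2 0.91, adjusted p = 0.000323). They included ACS5 (1.95 ± 0.12) and HLS1 (1.81 ± 0.16), which is needed for the apical hook. Cell wall expansion genes were higher in 15 of 26 and lower in 5 (15 and 6 adjusted over the list alone, median log2 0.31, adjusted p = 0.00206, adjusted p = 0.0521 with an estimated correlation). XTH19 stood at 2.26 ± 0.04. Clock genes were lower in 23 of 31 and higher in 6 (6 and 23 adjusted over the list alone, median log2 -0.42, adjusted p = 4.46e-05). PRR9 stood at -1.2 ± 0.13, GI at -0.64 ± 0.04 and LHY at 0.82 ± 0.05. Photoreceptor genes were lower in 6 of 9 and higher in 1 (1 and 6 adjusted over the list alone, median log2 -0.23, adjusted p = 0.0058, adjusted p = 0.0735 with an estimated correlation). PHYA and PHYB, the genes named by the genotype, are 2 of the 6. Flavonoid genes were higher in 9 of 17 and lower in 2, which did not pass as a list (9 and 2 adjusted over the list alone, median log2 0.18, adjusted p = 0.114), and CHS did not pass, at 0.01 ± 0.04 (adjusted p = 0.851). The anthocyanin regulator gene PAP1 was higher (0.81 ± 0.21) in the edgeR quasi-likelihood test but did not pass in the DESeq2 Wald test (adjusted p = 0.335). DFR, which acts late in anthocyanin synthesis, was 2.38-fold higher in the edgeR test, but did not pass in the DESeq2 Wald test (adjusted p = 0.0872) or without WT red replicate 1 (adjusted p = 0.0832).

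Seed storage and late embryo genes were higher in 9 of 9 tested members (9 and 0 adjusted over the list alone, median log2 3.58, adjusted p = 2.70e-05; the median is 3.22 with the member at 0 reads in WT red set to its bound). The filter keeps a gene with enough reads in 1 group, so members with few reads in every group were not tested. Members kept through phyAB red alone, among them CRU3, CRU2 and PAP85, were bound to come out higher there. The 9 of 9, the median and the adjusted p are therefore in part fixed by the filter. The 12S storage protein genes CRU3 (AT4G28520, 7.25 ± 0.27) and CRA1 (AT5G44120, 5.76 ± 0.24) rose. CRU2 was 32.5-fold higher, with a 95% counting interval of 8.66 to 273. The 2S storage gene SESA2 was at least 9.32-fold higher against 0 reads in WT red. Storage lipid genes were higher in 5 of 6 and lower in 1 (5 and 1 adjusted over the list alone, median log2 0.34, adjusted p = 0.0083, adjusted p = 0.0812 with an estimated correlation). ICL stood at 1.75 ± 0.03. Also among the genes with the highest changes were QRT1 (AT5G55590, 5.84 ± 0.17), which encodes a pectin methylesterase, GRF7 (AT5G53660, 4.91 ± 0.18), CYP96A5 (AT2G21910, 4.29 ± 0.22), AT3G27630 (4.2 ± 0.15), which encodes the cell cycle inhibitor SMR7, and EARLI1 (AT4G12480, 3.94 ± 0.08). Among genes with a mean of at least 5 CPM, the lowest besides CP12-2 were AT3G05950, with 3 reads in phyAB red and 173 in WT red, 64.0-fold lower with a counting interval of 21.5 to 313, the cell wall gene XTH6 (AT5G65730, -3.07 ± 0.20), the cineole synthase genes TPS-CIN (AT3G25820, -2.26 ± 0.04, and AT3G25830, -2.21 ± 0.04), which are near-identical copies, and MSRB6 (AT4G04840, -2.17 ± 0.06). Touch and wound genes were higher in 10 of 17 and lower in 4 (10 and 4 adjusted over the list alone, median log2 0.28, adjusted p = 0.0298, adjusted p = 0.111 with an estimated correlation; adjusted p = 0.0557 without phyAB red replicate 2). Phytochrome signalling genes were lower in 11 of 18 and higher in 4 (4 and 11 adjusted over the list alone, median log2 -0.25, adjusted p = 0.0435, adjusted p = 0.189 with an estimated correlation), and this call was lost without WT dark replicate 1 (adjusted p = 0.0518), WT dark replicate 2 (0.0517) or WT red replicate 1 (0.0814). The lists of PIF family, heat shock, brassinosteroid, gibberellin, root and stomatal genes did not pass.

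Across all tested genes, 4619 were higher and 4693 lower in phyAB red than in WT red in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, of which 850 and 612 changed by at least 2-fold. The largest adjusted p among the genes named as changed was 0.00455 (for DFR). The phyB and phyAB comparisons share the WT red libraries. Their shared calls were 874 higher and 1044 lower, against 605 and 656 from n1 × n2 / N for independent lists. Simulated unchanged groups gave 0 higher, but they hold no changed genes, so that 0 is no measure of overlap between changed sets. In opposite directions lay 1013 genes higher in phyB red and lower in phyAB red, and 833 the other way, against 614 and 646 for independent lists. Across genes, which are not independent replicates, the fold changes correlated at r = 0.175, with 0.523 in simulated unchanged groups. The covariance was 0.0436, the simulated covariance 0.0242 and the difference 0.0194. A split of the 2 WT red libraries would leave 1 for each mutant and was not made, so part of the excess of shared calls may come from the shared libraries. Calls in opposite directions also exceeded the number for independent lists. The excess in the same direction alone therefore does not show a common effect of the 2 genotypes.

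The comparison of phyAB red with phyB red sets the double mutant line against the single mutant line, and includes any other difference between these lines. PHYA itself was lower (-2.51 ± 0.03). Antenna genes were lower in 20 of 20 (0 and 20 adjusted over the list alone, median log2 -1.59, adjusted p = 1.88e-16). LHCB1.4 stood at -2.80 ± 0.03 and LHCA1 at -2.39 ± 0.02. Photosystem and Rubisco genes were lower in 26 of 26 (0 and 26 adjusted over the list alone, median log2 -1.48, adjusted p = 1.68e-20). All 8 photoprotection genes (0 and 8 adjusted over the list alone, median log2 -1.51, adjusted p = 1.99e-07) and all 13 carotenoid enzyme genes (0 and 13 adjusted over the list alone, median log2 -0.64, adjusted p = 3.58e-07) were lower, as were 20 of 26 chlorophyll synthesis genes with 2 higher (3 and 21 adjusted over the list alone, median log2 -0.69, adjusted p = 3.58e-07). ELIP2 (-2.49 ± 0.04), SIG5 (-2.73 ± 0.07), RUP1 (-2.18 ± 0.08) and MSRB6 (-3.14 ± 0.06) were lower, and PORA was higher (4.48 ± 0.05). B-box and HY5 factors were lower in 13 of 18 and higher in 3 (3 and 13 adjusted over the list alone, median log2 -0.96, adjusted p = 0.000763), and photoreceptor genes were lower in 8 of 9, PHYA and PHYB among them, and higher in 0 (0 and 8 adjusted over the list alone, median log2 -0.36, adjusted p = 4.16e-05). PIF-induced genes did not pass as a list, with 6 higher and 6 lower of 19 (7 and 7 adjusted over the list alone, median log2 -0.00, adjusted p = 0.983), and PIL1 stood at -0.00 ± 0.09 (adjusted p = 0.999). SAUR genes were lower in 23 of 26 and higher in 0 (0 and 23 adjusted over the list alone, median log2 -0.90, adjusted p = 6.00e-10). Among them were SAUR14 (-1.72 ± 0.08) and SAUR16 (-1.51 ± 0.08). Seed storage genes were higher in 9 of 9 tested members (9 and 0 adjusted over the list alone, median log2 4.62, adjusted p = 4.44e-05). The limit given above for the filter holds here too. AT3G27630 (5.25 ± 0.17), AT2G18193 (4.12 ± 0.06), the cellulase gene CEL2 (3.22 ± 0.16) and PAP1 (2.65 ± 0.26) were higher.

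Root genes were higher in 6 of 10 and lower in 0 (6 and 0 adjusted over the list alone, median log2 0.47, adjusted p = 0.0462, adjusted p = 0.137 with an estimated correlation), and this call was lost without WT red replicate 1 (adjusted p = 0.0676), WT red replicate 2 (0.0691), phyB red replicate 2 (0.0513) or phyAB red replicate 1 (0.0587). The flavonoid list, with 9 of 17 higher and 4 lower, did not pass (11 and 4 adjusted over the list alone, median log2 0.30, adjusted p = 0.0536), but passed without WT dark replicate 2 (adjusted p = 0.0499), WT red replicate 1 (0.042), WT red replicate 2 (0.0431) or phyB red replicate 1 (0.0492). In all, 5389 genes were higher and 4991 lower in phyAB red than in phyB red in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with 1014 and 902 at least 2-fold. The largest adjusted p among the genes named as changed was 6.67e-15 (for PAP1).

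The mutants were also placed between WT dark and WT red, gene by gene, as the part of the wild-type log2 change seen after red light, where 0 is the WT dark level and 1 the WT red level. Antenna genes lay at a median part of 1.11 in phyB red and 0.61 in phyAB red (19 genes), and photosystem genes at 1.1 and 0.54 (26 genes). Flavonoid genes had medians near the WT red level in both mutants, at 0.91 and 1.06 (12 genes). Single members ran from 0.16 to 1.08 in phyB red and from 0.84 to 1.44 in phyAB red. PIF-induced genes lay at 0.33 and 0.19 (13 genes), SAUR genes at -0.22 and 0.37 (16 genes) and clock genes at 0.95 and 0.33 (8 genes). Among the 1471 genes raised at least 2-fold in WT red, the median part was 1.06 in phyB red and 0.57 in phyAB red; 203 were lower in phyB red than in WT red and 1000 in phyAB red, while 481 were higher in phyB red. Among the 559 genes reduced at least 2-fold, the median part was 0.76 in phyB red and 0.21 in phyAB red, with 216 and 418 higher than in WT red. These parts describe the libraries and were not tested across genes. They share the wild-type libraries with the selection of the genes, and across genes the red response in wild type correlated with the phyB difference at r = -0.133 and with the phyAB difference at r = -0.542, against -0.521 and -0.52 in simulated unchanged groups. The covariances were -0.042 and -0.242, each -0.0242 in the simulation, which left differences of -0.0177 and -0.218.

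**Figure D3:**
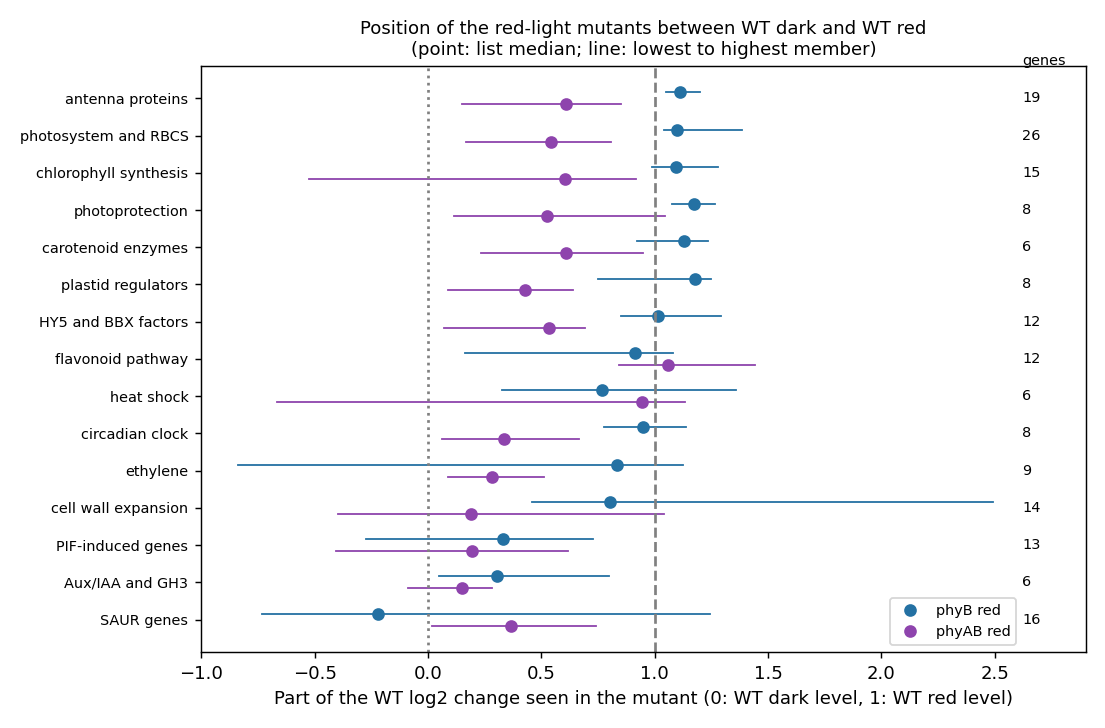
Part of the wild-type log2 change seen in phyB red and phyAB red (horizontal axis, 0 for the WT dark level and 1 for the WT red level, no unit) for the genes of each list changed at least 2-fold in WT red, whose number stands at the right. Points are list medians and lines run from the lowest to the highest member; antenna genes lay at 1.11 in phyB red and 0.61 in phyAB red.

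Set directly against WT dark, where genotype and light differ together, phyAB red still showed higher LHCB2.1 (3.86 ± 0.06) and CHS (5.30 ± 0.08). All 26 photosystem and Rubisco genes were higher (26 and 0 adjusted over the list alone, median log2 1.47, adjusted p = 1.92e-18), as were 15 of 17 flavonoid genes with 0 lower (15 and 0 adjusted over the list alone, median log2 2.54, adjusted p = 1.82e-09). PORA was higher than in WT dark (1.46 ± 0.03) and HY5 lower (-0.30 ± 0.08), while IAA29 (-0.03 ± 0.13, adjusted p = 0.866) and PRR9 (0.19 ± 0.16, adjusted p = 0.339) did not pass. SAUR genes were lower in 21 of 26 and higher in 1 (1 and 21 adjusted over the list alone, median log2 -0.46, adjusted p = 1.52e-06). In phyB red, all 26 photosystem and Rubisco genes (26 and 0 adjusted over the list alone, median log2 2.98, adjusted p = 8.42e-22) and all 20 antenna genes (20 and 0 adjusted over the list alone, median log2 3.28, adjusted p = 5.06e-18) were higher than in WT dark, and SAUR genes were higher in 18 of 26 and lower in 0 (20 and 0 adjusted over the list alone, median log2 0.35, adjusted p = 0.000429, adjusted p = 0.0568 with an estimated correlation). In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 5678 genes were higher and 5622 lower in phyB red than in WT dark, and 5637 higher and 4349 lower in phyAB red than in WT dark. At least 2-fold, these were 1663 and 614 for phyB red and 1300 and 213 for phyAB red.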

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

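Of the settings in this part, the fixed coefficient of variation and the counts of genes changed at least 2-fold were chosen after the result was seen. The 14 counts of genes stayed within 1.5 times with DESeq2 size factors, no filter on low counts, fits of only the groups compared, limma-voom, no organelle genes and each of the 8 libraries left out. The replicate numbers do not pair the libraries in the labels, and deviations of libraries with the same number correlated at -0.0036 to 0.027. With a replicate block, all 14 counts stayed within 1.5 times. The list of photoreceptors in phyAB red against WT dark no longer passed in the camera test (adjusted p = 0.0507). PIF4 no longer passed in that comparison in the edgeR quasi-likelihood test (adjusted p = 0.0501). No other list call changed and no other named gene call was lost. Named genes that had not passed were not tried again under the alternatives. No named gene call, list call or median part reversed in direction. Of 11676 alternative values of 687 named gene results that had passed, 11110 kept the call and 566 did not pass. The balance between genes called higher and lower did turn in some settings, as given below. The cause of the changes below was not tested, except that a fold threshold and a larger spread leave fewer genes by construction. Of genes with the smallest simulated change, 48% to 50% were recovered.

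The DESeq2 Wald test gave 1740 genes higher and 1912 lower in phyB red against WT red, and 542 higher and 663 lower in both mutants. An adjusted p under 0.01 left 582 genes higher in both mutants. Tested against a 2-fold change, the genes higher and lower were 951 and 245 in WT red against WT dark, 63 and 56 in phyB red against WT red, 336 and 268 in phyAB red against WT red, 441 and 495 in phyAB red against phyB red, 1076 and 266 in phyB red against WT dark, 648 and 77 in phyAB red against WT dark, and 24 and 10 in both mutants. With a fixed coefficient of variation of 0.1 they were 3130 and 1923, 649 and 672, 2261 and 2096, 3068 and 2700, 3638 and 2815, 3150 and 1592, and 246 and 131 in the same order. Called and changed at least 2-fold were 1471 and 559, 241 and 219, 850 and 612, 1014 and 902, 1663 and 614, 1300 and 213, and 103 and 31. Higher genes made up 51.4% of calls in WT red against WT dark, 79.5% when tested against a 2-fold change and 61.9% with the fixed variation. In phyB red against WT dark they made up 50.2% and 80.2% when tested against a 2-fold change, and in phyAB red against WT dark 56.4%, 89.4% and, with the fixed variation, 66.4%. Other settings took this share down: without WT dark replicate 1 or 2 it was 46.4% and 45.8% in WT red against WT dark, 46.3% and 46.1% in phyB red against WT dark, and 49.6% and 49.8% in phyAB red against WT dark. It was 49.2% in WT red against WT dark with DESeq2 size factors, and 49.9% in phyAB red against WT dark with only the groups compared in the fit.

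The median part of the wild-type response, as reported, was 1.06 for raised genes and 0.76 for reduced genes in phyB red, and 0.57 and 0.21 in phyAB red. The DESeq2 Wald test moved it to 1.069 for raised genes in phyB red and to 0.562 and 0.207 in phyAB red. The test against a 2-fold change gave 1.077, 0.549 and 0.173 for these. No filter gave 0.563 and 0.23 in phyAB red, and fits of only the groups compared 0.561 and 0.239. Genes chosen on wild-type libraries numbered 1 and measured on those numbered 2 gave 1.086 for raised genes in phyB red and 0.555 and 0.206 in phyAB red, and the reverse gave 1.076, 0.561 and 0.234. The fixed lists of antenna and PIF-induced genes gave 1.11 and 0.333 in phyB red and 0.609 and 0.193 in phyAB red. Leaving out 1 library gave 1.057 to 1.073 for raised and 0.688 to 0.784 for reduced genes in phyB red, and 0.558 to 0.574 and 0.188 to 0.288 in phyAB red.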

Other observations

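Among the tests below, that of wild-type material mixed into the phyAB libraries was chosen only after the result was seen, as were the comparison of cell division genes with the 15 damage genes and their split into replication and other genes. The sets of DNA damage and cell division genes were composed after the pattern was noticed but before the values of the members not yet seen were read.

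Outside the fixed lists, genes of the response to DNA damage were higher in phyAB red than in WT red. They included the cell cycle inhibitor gene SMR7 (AT3G27630, log2 fold change 4.2 ± 0.15, SE, n = 2 libraries per group), PARP2 (3.18 ± 0.11), the ribonucleotide reductase gene TSO2 (2.98 ± 0.04), BRCA1 (2.96 ± 0.13) and XRI1 (2.75 ± 0.09). These belong to 10 genes that were picked after their values were seen, all at least 2-fold higher in phyAB red than in WT red and than in WT dark. In phyB red against WT red, 0 of the 10 were higher and 2 lower in the edgeR quasi-likelihood test. They are part of a larger set: 251 of 19084 genes with a mean of at least 1 CPM lay at least 2-fold outside both wild-type groups in phyAB red, 216 above and 35 below. In phyB red 125 genes did so, 56 above and 69 below, and 14 were outside in the same direction in both mutants.

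For these 251 genes, chromosome segments of another origin linked to PHYA or PHYB were one explanation weighed. Of them, 18 lay within 2 Mb of either gene, against 1501 of all 19084. The odds ratio was 0.904 (95% interval 0.525 to 1.47, Fisher's exact test, two-sided, p = 0.813), which argues against linked segments for the set as a whole. They stay open for single genes among the 18, such as AT2G18193 and AT2G18540, which start at 7917413 and 8042096 on chromosome 2, near PHYB. A larger share of dividing cells was weighed as well. If both sets follow that share alike, replication and mitosis genes would rise as far as the 10 damage genes first noticed. That premise was not tested. The 14 replication and mitosis genes had a median of 0.35 with 0 at least 2-fold higher, against 2.64 for the 10. Since the 10 were picked as high, a gap in medians was likely from the start. Under that premise, the 14 argue against more dividing cells as the whole cause for those 10, all at least 2-fold higher. More dividing cells stay open for the 15 other damage genes below. Their median lay 0.70 above that of the 14, with half-ranges of 0.73 together. A smaller rise in replication is open too, since 7 of 8 MCM and PCNA genes were higher against 1 of the 6 others. As a hypothesis, part of the pattern may be an active DNA damage response in the phyAB seedlings: 15 tested damage genes not seen before had a median of 1.05 against WT red (interquartile half-range 0.45), just past the value of 1 set for it, with 12 higher and 1, KU70, lower (-1.15 ± 0.09), but a median of 0.97 against WT dark, with 12 higher and 2 lower. What would start such a response, the loss of the receptors, another mutation in the line or the state of the seedlings, cannot be decided with 1 double mutant line and no dark mutant library.

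The second pattern weighed is the rise of seed storage transcripts in phyAB red. CRU3 and CRA1 reached 26.8 and 21.8 CPM there, and as a hypothesis seed or late embryo tissue in the phyAB libraries, from ungerminated or delayed seeds, could be a source: the other 7 tested members of the list had a median of 2.86 (interquartile half-range 0.94), and 7 of 7 were higher. Of the 9 tested members, 2 had at least 1 CPM in WT red and 8 in phyAB red. The filter on low counts can keep a member through its reads in phyAB red alone. CRU3, CRU2 and PAP85, all under 1 CPM in every other group, were among the members kept in this way. CRU3 had 6 reads in WT dark, 6 in WT red and 7 in phyB red, against 1051 in phyAB red. The 7 of 7 and the median are therefore in part fixed by the filter. Seedlings that keep part of the seed programme would show the same, and the data do not separate these.

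The third pattern is the part of the light response still present in phyAB red, where 1245 of the 1471 genes raised at least 2-fold in WT red were also higher than in WT dark. Wild-type seedlings or reads mixed into these libraries would give every strongly changed gene about the same part of the wild-type change in CPM. This holds only where phyAB seedlings without such material stand at the WT dark level. Over 603 genes the interquartile range of that part was 0.307 (quartiles 0.221 and 0.528) around a median of 0.33. These values argue against mixing as the only difference from WT dark. They leave open mixing together with genotype differences, which would also spread the part. PHYA does not decide: it lay at 124 CPM against 154 CPM for a mixture at the median part, and within the 103 to 247 CPM of the quartiles. A difference between the genotypes already present in darkness may account for any of the 1245 genes and cannot be told apart from a response through other receptors, since dark phyAB libraries are not analysed here. Such a response was not tested.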
